A study of Homo sapiens with 9 samples.

How the data were processed

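The study compared SNB19 and U251 glioblastoma cells transfected with the FGFR3-TACC3 fusion, wild-type FGFR3 or wild-type TACC3 with cells that carried the empty vector. Per the labels, 600000 cells were transfected and selected for 2 weeks in 0.4 mg/ml G418. Each of the 9 dual-channel Agilent arrays carried RNA of transfected cells and of vector cells of the same line in opposite dyes. The transfected sample was in Cy3 on 4 arrays (the 3 SNB19 fusion clones and their mixture) and in Cy5 on 5, and 6 arrays were of SNB19 and 3 of U251.

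The deposited values are log10 ratios of both channels, made by the authors with Agilent Feature Extraction 9.1.3.1 per the submitters' processing notes. The table states neither the log base nor the direction of the ratio. The base of 10 was taken from the software's usual output and the number format, so folds rest on that reading. The median of each column was 0, and 15.9% to 25.5% of the 45015 features on an array were exactly 0. Medians over the nonzero values of named genes ran from -0.0472 on the SNB19 TACC3 array to 0.00516 on the U251 fusion array, so the median of 0 does not show that values were centred. The base remains a reading from the format, and the direction remains likely for the Cy3 arrays and unknown for the Cy5 arrays. Background correction, dye normalization and signal intensities are not given in the sources used here, so no filter on signal could be applied. All 9 value columns were used.

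The platform annotation gave 1 gene symbol for 31332 features, several symbols for 93 and none for 13590. Features with 1 symbol made up 18334 genes, of which 10575 had 1 probe and 7759 had several, and the value of a gene was the mean over its probes on each array. Matching 31291 probes by their Entrez number changed 0 symbols. Of the features, 2999 were at 0 on all arrays. Genes at exactly 0 on all arrays of a fit were left out of that fit. No coordinates are given, since no genome build was named for the values.

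The comparisons, the rule for naming genes, the direction rule, 17 gene lists and the alternatives were fixed before the data were examined. By the direction rule, the probes of the transfected genes were read within each dye. The sign was called where they lay beyond the 99th percentile of sizes on most arrays of that dye with 1 sign, since a construct can only raise its own transcript. The rule assumes that these probes lie within the transfected sequences, which is not given in the sources used here.

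Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all genes of a fit and a threshold of 0.05. The 3 SNB19 clones were tested for a mean ratio different from 0, with 2 residual degrees of freedom. This test leaves out the spread of the vector cells, and the mixture was kept out because it holds the same clones. The other comparisons used 8 arrays without the mixture. One model held means for SNB19 fusion, U251 fusion, FGFR3 and TACC3, and another held a mean per construct and a dye term, each with 4 residual degrees of freedom. Groups of 1 array have no check between replicates. A single array was assumed to vary like the other groups.

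The named genes in the clones were the 12 highest and 12 lowest mean ratios among genes past the test with 1 sign in the 3 clones and the mixture. For the wild-type constructs and the contrasts between constructs, the rule took up to 6 genes per direction past the test or, where fewer than 3 passed, the 3 with the largest sizes, given as values that did not pass. Where 2 arrays served, the smaller of both sizes ranked the genes and both had to share a sign. For the U251 fusion array the 6 highest and 6 lowest ratios were named. From each list up to 4 members with the largest sizes were named, and a few further members of lists were named after their values were seen. Genes without a standard symbol and genes of the Y chromosome were not named.

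The 17 lists held 362 entries (353 distinct genes), of which 340 were on the arrays. They covered ERK output, STAT3 targets, interferon response, NF-kB and inflammatory cytokines, DNA replication, mitosis and spindle, the FGF pathway, TACC family and partners, mitochondrial respiration, hypoxia and glycolysis, mesenchymal and matrix genes, neural and glial genes, cholesterol synthesis, stress response, p53 targets, ribosomal proteins and markers of other cell types. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 17 lists of a comparison. On single arrays the median of a list was set against 10000 random lists of the same size, which were not matched on expression because the table gives ratios only.

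The test was tried on simulated ratios with the spread of the arrays and 200 changed genes. With 3 clones it recovered 14%, 50%, 84% and 90% of genes at true sizes of 0.15, 0.3, 0.6 and 1, with 3 false calls among 16896 genes. For wild-type FGFR3 it recovered 0%, 20%, 62% and 94% with 6 false calls, and for the fusion in both lines 0%, 36%, 76% and 100% with 9 false calls among 17614 genes. The simulated errors were normal, centred on 0 and independent between arrays. They held no error of a shared vector RNA and, except for the fusion in both lines, no dye bias. The clone test called 4743 genes in the data, far more than were changed here. The simulated recovery and false calls therefore do not carry over to the data.

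Alternatives were a subtracted array median, arrays scaled to 1 median size, each probe on its own, the median over probes, probes at 0 on any array left out, robust eBayes, each clone left out, the mixture as a 4th array, a fit over 8 arrays, models with and without the dye term, the Cy3 signs turned and the cell line as a block. Leaving out each wild-type array, list tests with the Cy3 signs turned and subtracting the median from the U251 fusion array were added after the data were seen. A fit without 1 wild-type array rests on 1 array of that construct, so its counts have no replicate. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.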

Results

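Expression was profiled on 9 dual-channel Agilent microarrays in SNB19 and U251, established human glioblastoma cell lines. The cells had been stably transfected with the FGFR3-TACC3 fusion, with wild-type FGFR3 or with wild-type TACC3. FGFR3 is a fibroblast growth factor receptor tyrosine kinase, and TACC3 is a coiled-coil protein of the mitotic spindle. Each array set 1 transfected sample against cells of the same line that carried the empty vector, so each value is a ratio of transfected and vector cells on 1 array. The fusion was measured in 3 SNB19 clones (2, 5 and 8), in a mixture of the same 3 clones and in U251. Each wild-type construct was measured on 1 array per line. No array held vector cells against vector cells. The labels do not say that the clones were grown or hybridised more than once, so p-values over the 3 clones measure the spread between these arrays. The number of arrays limits the precision, and the SD over the 45015 features ran from 0.110 on the U251 fusion array to 0.247 on the SNB19 TACC3 array. Values are log10 ratios, and the base of 10 was taken from the scanner software's usual output.

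The direction of the ratios was read from the probes of the transfected genes. TACC3 (feature 36027) had a log10 ratio of 0.598 in clone 2, 0.881 in clone 5, 0.868 in clone 8 and 0.638 in the mixture. These 4 arrays carried the sample in Cy3, and TACC3 lay beyond the 99th percentile of all sizes on 3 of them. A construct can only add its own transcript, so if the TACC3 probe reads the construct, a positive value on these arrays is likely transfected over vector. Whether it lies within the transfected TACC3 sequence is not given in the sources used here, and every direction given for the clones rests on it. The software's usual output runs Cy5 over Cy3, the reverse of this reading. Under that output, genes called higher in the clones would be lower, and the reverse. The other 5 arrays carried the sample in Cy5. There TACC3 was at -0.574 in U251 fusion cells, -0.352 in SNB19 TACC3 cells and -0.168 in U251 TACC3 cells, and only the U251 fusion value passed the 99th percentile. The direction of these 5 arrays was not settled. Their values are therefore given as deposited, as sizes with a sign of unknown direction. Where results combine both kinds of array, gene counts, TACC3 and camera list tests are also given with the sign of the Cy3 arrays turned. Values of single list members, counts under other settings and fry calls are as deposited only. Turned values apply if the Cy5 arrays run vector over transfected. All would then run that way, so a negative turned value would mean higher in transfected cells. The 2 FGFR3 probes (features 11667 and 33329) stayed within 0.212 of 0 on all 9 arrays. Their position is not given either, and their values check neither the constructs nor the direction.

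**Figure D1:**
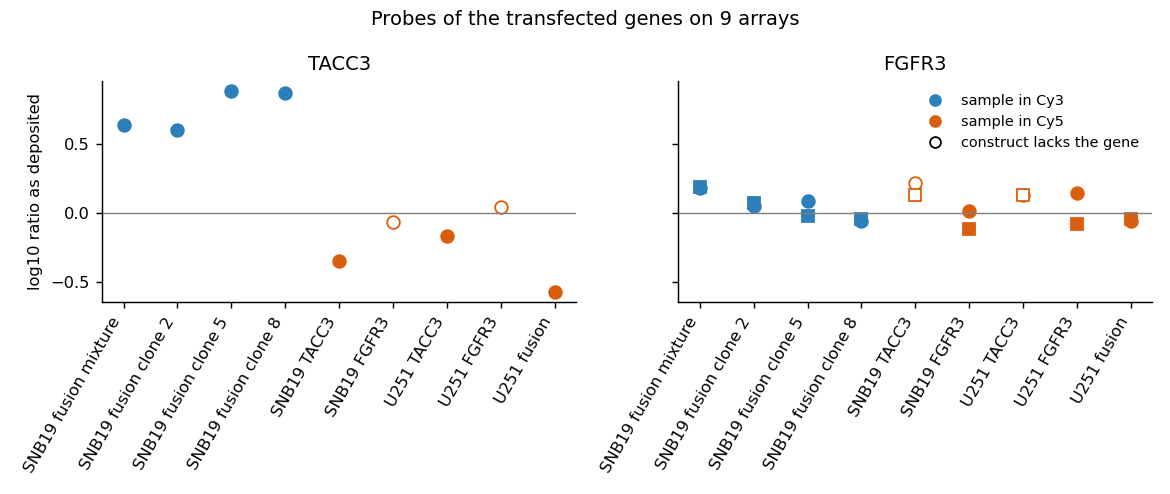
Deposited log10 ratio (vertical axis) of the TACC3 probe and of the 2 FGFR3 probes (circles and squares) on each of the 9 arrays (horizontal axis), coloured by the dye of the transfected sample, with open symbols where the construct lacks the gene. TACC3 lies at 0.598 or above on the 4 Cy3 arrays and at -0.168 or below on the 3 Cy5 arrays whose construct carries it.

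The first comparison asked which genes differed between SNB19 cells carrying the fusion and SNB19 cells carrying the vector. TACC3 itself was at 0.782 ± 0.160 (SD, n = 3), a 6.06-fold difference (adjusted p = 0.0160). Its sign set the direction, so that it was higher restates that rule and is no separate result. FGFR3 did not pass at 0.0132 ± 0.0587 (adjusted p = 0.745). The highest ratio was that of the protease inhibitor A2M, at 1.81 ± 0.0922, or 64.8-fold over vector cells. The matricellular protein SPARCL1 followed at 1.57 ± 0.169 (37.5-fold), and the collagen gene COL11A1 at 1.39 ± 0.140 (24.8-fold). The choline transporter-like gene SLC44A5 stood at 1.32 ± 0.0860 and the protocadherin PCDH20 at 1.22 ± 0.387. The immediate-early transcription factor FOS was 10.8-fold higher, at 1.03 ± 0.115, and the glial receptor phosphatase PTPRZ1 9.93-fold higher, at 0.997 ± 0.0480. RPE65, the retinoid isomerase of the visual cycle, CALCRL, a receptor of calcitonin family peptides, and NLGN4X, a synaptic adhesion protein, lay at 1.19, 1.11 and 1.08. PKIB, an inhibitor of protein kinase A, and SLC16A7, a monocarboxylate transporter, were at 0.976 and 0.962.

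Among the lower genes, PLAC8 had the largest size, at -1.49 ± 0.0443, or 30.6-fold below vector cells. The adhesion receptor ADGRE1, better known from macrophages, was at -1.39 ± 0.0673 (24.5-fold lower). INHBA, which encodes the activin A subunit, was at -1.35 ± 0.142 (22.5-fold lower). The acute-phase gene SAA1, LY6E and the bradykinin receptor gene BDKRB2 lay between -0.904 and -0.891. RHEX stood at -0.870, the epidermal gene LCE3D at -0.819 and TMEM204 at -0.797. The sorting receptor SORCS2 was at -0.790 ± 0.416, the olfactory receptor OR51B5 at -0.786 ± 0.0410 and RSPO3, a secreted enhancer of WNT signalling, at -0.760 ± 0.0450. All 24 of these genes had the same sign in the 3 clones and in the mixture, as the rule for naming required. Large sizes at some of them were not confined to fusion cells. On the SNB19 FGFR3 array, as deposited with no settled direction, PLAC8 was at -1.29, INHBA at -1.24 and A2M at -1.06. Others were small there, such as FOS (-0.0116) and SAA1 (-0.0973). On the SNB19 TACC3 array PLAC8 was at -0.256, INHBA at -0.287 and A2M at 0.194.

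In total 4743 of 16896 tested genes passed an adjusted p of 0.05 with limma, 2493 higher and 2250 lower, and 608 of them differed at least 2-fold. Without clone 5 or without clone 8 no gene passed (4650 and 4953 genes at an unadjusted p under 0.05), and without clone 2 the count was 3456. With the mixture added as a 4th array it was 2474, with each probe tested on its own it was 8686 of 28622 probes, and in a fit over 8 arrays it was 680. The test leaves out the spread of the vector cells, all 3 arrays have 1 dye orientation, and 17 of 82 tested olfactory receptor genes, silent in most tissues, also passed (20.7%, against 28.1% of all genes).

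**Figure D2:**
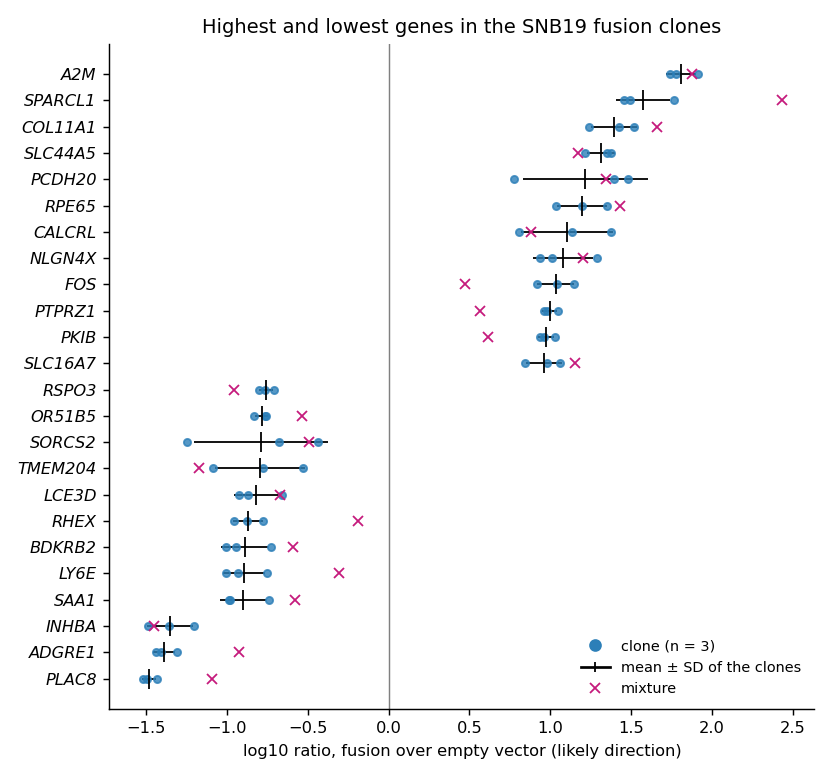
Log10 ratio (horizontal axis) of the 12 highest and 12 lowest named genes (vertical axis) in the SNB19 fusion clones: dots are the 3 clones, black marks with bars the mean ± SD, and crosses the mixture array. A2M lies highest at a mean of 1.81 and PLAC8 lowest at -1.49, and every cross falls on the same side of 0 as its clones.

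Of 23 measured genes known as transcriptional output of ERK signalling, 13 were higher in the clones, 0 were lower and 10 did not pass, with a median log10 ratio of 0.227 (camera adjusted p = 8.51e-05; adjusted p = 0.523 with an estimated correlation). Adjusted over the list alone, 18 were higher and 2 lower, the ephrin receptor EPHA2 at -0.131 and the neuropeptide precursor VGF at -0.0695. The immediate-early factor EGR1 had the largest size at 0.949 ± 0.207 (8.89-fold). It was followed by DUSP6, a phosphatase that switches ERK off, at 0.568 ± 0.107 (3.70-fold), SPRY2, a feedback inhibitor of receptor tyrosine kinases, at 0.543 ± 0.0883 (3.49-fold), and the ephrin receptor EPHA4 at 0.358 ± 0.0479. The ETS factors ETV1, ETV4 and ETV5 were higher at 0.358, 0.260 and 0.307. CCND1 did not pass, at 0.0822 (adjusted p = 0.131). STAT3 targets were higher for 9 of 20 genes and lower for 0, with a median of 0.0856 (camera adjusted p = 0.0171; adjusted p = 0.523 with an estimated correlation), and 10 were higher adjusted over the list alone. FOS led them, and the acute-phase serpin SERPINA3 (0.513 ± 0.113), the NF-kB cofactor BCL3 (0.308 ± 0.0505) and the angiogenic factor VEGFA (0.223 ± 0.0904) followed, while STAT3 itself was at -0.0392 and did not pass (adjusted p = 0.134). The ERK and STAT3 lists share CCND1 and MYC, of which MYC was higher at 0.140.

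Genes of hypoxia and glycolysis were higher for 10 of 21 and lower for 0, with a median of 0.126 (camera adjusted p = 0.00313; adjusted p = 0.523 with an estimated correlation), and 11 were higher adjusted over the list alone. The secreted lipase inhibitor ANGPTL4 was 7.59-fold higher, at 0.880 ± 0.175. The collagen hydroxylase P4HA1 was at 0.461 ± 0.0811, the glucose transporter SLC2A3 at 0.362 ± 0.180 and the demethylase KDM3A at 0.247 ± 0.0331. LDHA, at -0.0501, did not pass (adjusted p = 0.337). Mitochondrial respiration went the other way, with 8 of 23 genes lower and 0 higher at a median of -0.0678 (camera adjusted p = 0.00484; adjusted p = 0.523 with an estimated correlation), and 10 lower and 2 higher adjusted over the list alone. PPARGC1A, a coactivator that drives mitochondrial biogenesis, was at -0.376 ± 0.0364, or 2.38-fold lower. The complex I subunits NDUFS1 and NDUFB3 were at -0.178 and -0.156, and UQCRC2 of complex III at -0.150.

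The NF-kB and inflammatory cytokine list had 7 of 18 genes higher and 2 lower, with a median of 0.170 (camera adjusted p = 0.0453; adjusted p = 0.523 with an estimated correlation), the same counts adjusted over the list alone. IL6 was at 0.352 ± 0.0536, IL1B at 0.220 ± 0.0188 and the neutrophil chemokine CXCL2 at 0.213 ± 0.106, whereas NFKBIA, the inhibitor that NF-kB induces, was lower at -0.238 ± 0.0358. Stress response genes were higher for 6 of 18 and lower for 0 at a median of 0.0389 (camera adjusted p = 0.0273; adjusted p = 0.523 with an estimated correlation), 7 of them higher adjusted over the list alone. These were led by VLDLR (0.276 ± 0.0133), ATF3 (0.274 ± 0.0147), SESN2 (0.168 ± 0.0358) and the asparagine synthetase ASNS (0.166 ± 0.0167). DDIT3 and HSPA5, markers of the unfolded protein response, did not pass at -0.00849 and 0.00773. The camera call was lost without clone 8 for the NF-kB and stress lists and without clone 5 for the stress list.

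The other 11 lists did not pass camera. Mitosis and spindle genes were lower for 8 of 24 and higher for 2 (camera adjusted p = 0.136), or 8 and 3 adjusted over the list alone. Among them TTK, the spindle checkpoint kinase, was higher at 0.136 ± 0.0222, while the mitotic kinase PLK1 (-0.125 ± 0.0183), CENPF (-0.113 ± 0.0340) and CDK1 (0.120 ± 0.0398) went both ways. DNA replication had 3 genes higher and 3 lower of 24, as it had adjusted over the list alone. TACC family members and partners had 0 higher and 4 lower of 12, with TACC1 at -0.148 ± 0.0327, and 1 higher and 4 lower adjusted over the list alone. Neural and glial genes were higher for 8 of 22 and lower for 3 (camera adjusted p = 0.176), or 8 and 5 adjusted over the list alone. PTPRZ1 led, the radial glia gene FABP7 stood at 0.525 ± 0.0429 and the astrocyte filament gene GFAP at 0.416 ± 0.141, while the adhesion molecule L1CAM was lower at -0.453 ± 0.151. Of the p53 targets, 7 of 14 were higher and 3 lower (9 and 3 adjusted over the list alone), with GDF15 at 0.719 ± 0.279. Mesenchymal and matrix genes had 5 higher and 4 lower of 27 (6 and 4 adjusted over the list alone), with the protease MMP3 at -0.697 ± 0.214 and the collagen crosslinker LOX at -0.409 ± 0.0383. Interferon response genes had 4 higher and 6 lower of 24 by both counts, with IFIT2 at 0.412 ± 0.0276 and MX2 at -0.411 ± 0.192. Cholesterol synthesis had 4 higher and 1 lower of 13 (5 and 1 adjusted over the list alone). With the same counts over all genes and adjusted over the list alone, ribosomal proteins had 4 higher and 1 lower of 21, and the FGF pathway 3 higher and 2 lower of 18, with the ligand FGF2 at -0.225 ± 0.0765. Among markers of other cell types, 2 of 16 were higher and 5 lower by both counts, including the epithelial keratin KRT19 at -0.432 ± 0.0891.

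**Figure D3:**
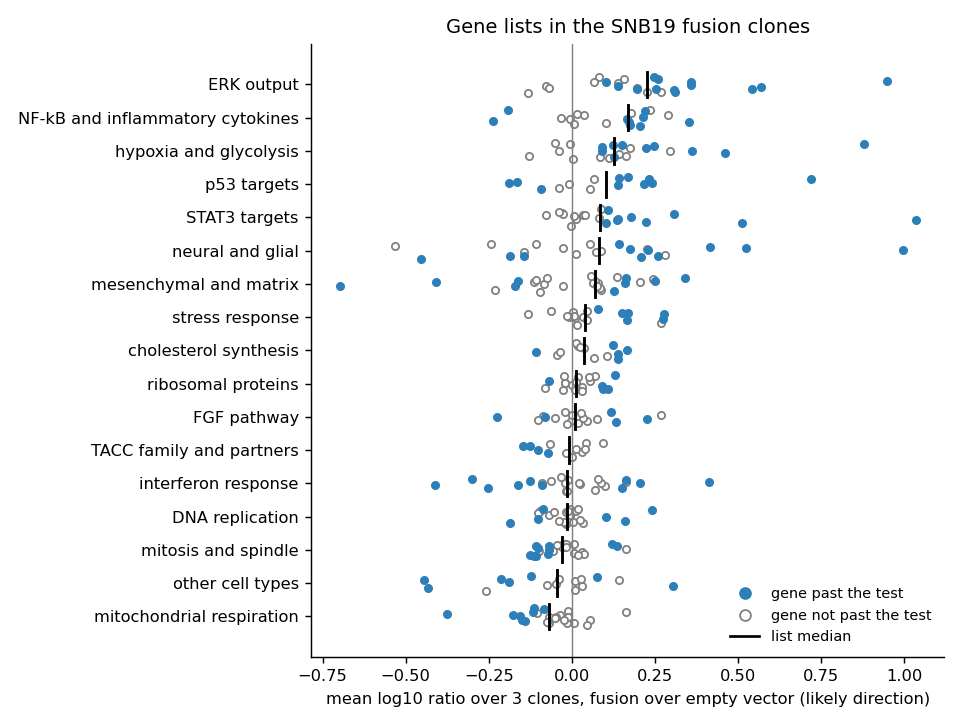
Mean log10 ratio over the 3 SNB19 fusion clones (horizontal axis) of each measured member of the 17 gene lists (vertical axis, ordered by median); filled dots passed the test over all genes, open dots did not, and black bars are list medians. The ERK output list has the highest median at 0.227 and mitochondrial respiration the lowest at -0.0678.

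The mixture pooled the same 3 clones and was set against them as a technical comparison, with no test. Across 17676 genes, which are not independent replicates, its ratios followed the mean of the clones with Pearson's r = 0.501 (Spearman's rho = 0.468) and a slope of 0.835. Each clone left out in turn followed the mean of the others with r between 0.682 and 0.818. The median of the ERK output list on the mixture array was 0.0369, with 13 of 23 genes positive, at percentile 86.6 of 10000 random lists of the same size. EGR1 was at -0.203 and DUSP6 at 0.0369, while SPRY2 was at 0.422. The medians of hypoxia and glycolysis (-0.0156, percentile 21.2), NF-kB and inflammatory cytokines (-0.00792, percentile 30.7) and mitochondrial respiration (-0.0254, percentile 15.5) also lay within the range of random lists there, whereas STAT3 targets (0.204) and stress response (0.419) were above percentile 99. The differences from the clones were not tested. SPARCL1 reached 2.44 on the mixture, above all 3 clones (1.46 to 1.77).

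The next comparison asked for fusion effects common to SNB19 and U251, with dye as a term of the model. With the deposited signs no gene passed in limma (0 of 17614, smallest adjusted p = 0.122, 1568 at an unadjusted p under 0.05), and with the sign of the Cy3 arrays turned none passed either (smallest adjusted p = 0.0992, 1504 unadjusted). Scaling the arrays to 1 median size gave 1008 genes, testing each probe gave 1 (LRRC8B, -0.790) and leaving out probes at 0 on any array gave 2 genes (CFAP43, -0.753, and STK32B, -0.695), which are named here after their values were seen. TACC3 was at 0.104 with the deposited signs (adjusted p = 0.829), the mean of a positive SNB19 and a negative U251 value, and at -0.678 with the Cy3 signs turned. Camera called 4 of the 17 lists with the deposited signs: hypoxia and glycolysis (median 0.0649, adjusted p = 0.0126), ERK output (0.0499, adjusted p = 0.0202), STAT3 targets (0.0331, adjusted p = 0.0203) and mitochondrial respiration (-0.0425, adjusted p = 0.0351). With an estimated correlation none held, at adjusted p = 0.701 for the first and second and adjusted p = 0.442 for the others. With the Cy3 signs turned camera called 5 lists: ERK output (median -0.172, adjusted p = 1.46e-11), hypoxia and glycolysis (-0.0629, adjusted p = 0.00161), NF-kB and inflammatory cytokines (-0.0843, adjusted p = 0.00295), STAT3 targets (-0.0551, adjusted p = 0.00295) and stress response (-0.0424, adjusted p = 0.0130). Turned medians would run vector over transfected, so the negative ones would mean higher in fusion cells over both lines. Mitochondrial respiration was then not called (0.0225, adjusted p = 0.122). With an estimated correlation these 5 were at adjusted p = 0.126 to 0.362. With the deposited signs, 6 members of the 17 lists passed adjusted over the list alone and none passed over all genes. These were P4HA1 (0.276) of the hypoxia list, the STAT3 targets FOS (0.376) and SERPINA3 (0.217), the neural and glial genes PTPRZ1 (0.419) and OLIG2 (-0.425), and the p53 target RRM2B (0.177). With the Cy3 signs turned none passed over all genes either. Adjusted over the list alone, 9 ERK output, 3 mesenchymal and matrix, 2 STAT3, 1 neural and glial and 1 stress response genes then passed.

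On the U251 fusion array itself, which had no replicate, the largest positive deposited ratios were those of SPATA8 (0.727), the neural gene NELL2 (0.604), NKPD1 (0.592), GPR45 (0.589), GSC2 (0.559) and ADCY4 (0.553). The largest negative ones were those of TRIM49 (-1.21), the calcium-binding protein gene NECAB2 (-0.905), CLCA3P (-0.859), the leukotriene receptor CYSLTR2 (-0.841), OR4C46 (-0.833) and NPTX2 (-0.817). TRIM49, CLCA3P, CYSLTR2 and NPTX2 were below 0 on all 9 arrays. The median of the ERK output list was -0.102 on this array, with 3 of 23 genes positive, below all 10000 random lists of the same size. This was not particular to the fusion in U251. The list was at -0.0772 on the U251 TACC3 array (1 of 23 positive, below all random lists). On the U251 FGFR3 array it was at -0.0419 (6 of 23 positive, percentile 0.55). The mitosis and spindle list had a median of 0.0481, with 22 of 24 genes positive.

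The fusion effect was then compared between the lines, as U251 minus SNB19 clones. No gene passed in limma (smallest adjusted p = 0.0992, 1504 of 17614 at an unadjusted p under 0.05), and scaling the arrays to 1 median size gave 1011. Turning the Cy3 signs also gave 0 (smallest adjusted p = 0.122). TACC3 differed by -1.36 as deposited (adjusted p = 0.122) and by 0.208 with the Cy3 signs turned. The ERK output list had a median difference of -0.345 as deposited, with 20 of 23 values below 0 (camera adjusted p = 1.46e-11; adjusted p = 0.126 with an estimated correlation). Of its genes 0 passed over all genes, and 9 passed adjusted over the list alone. EGR1 differed by -1.38, DUSP6 by -0.814, SPRY2 by -0.761 and DUSP5 by -0.517, none past the test over all genes. Camera also called NF-kB and inflammatory cytokines (median -0.169, adjusted p = 0.00295; adjusted p = 0.126 with an estimated correlation), STAT3 targets (-0.110, adjusted p = 0.00295; adjusted p = 0.126 with an estimated correlation), hypoxia and glycolysis (-0.126, adjusted p = 0.00161; adjusted p = 0.362 with an estimated correlation) and stress response (-0.0848, adjusted p = 0.0130; adjusted p = 0.362 with an estimated correlation). Adjusted over the list alone, 2 STAT3 targets (FOS, -1.32, and SERPINA3, -0.593) and 1 stress gene (ATF3, -0.470) passed. From lists that camera did not call, PTPRZ1 (-1.16) passed in the same way, as did the mesenchymal and matrix genes CCN2 (-0.329), LOX (0.459) and MMP3 (0.748). The fry test called ERK output, NF-kB and STAT3 targets (adjusted p = 0.0236 each). U251 rests on 1 array that is assumed to vary like the other groups, and dye and cell line cannot be told apart here. The deposited ERK output median was negative on the U251 wild-type arrays too, so its U251 shift was not particular to the fusion. With the Cy3 signs turned, the contrast as deposited is the sum of both lines, which is 2 times their mean, so the same list values would then describe that sum, not how the lines differ. All turned values would run vector over transfected. A positive difference would thus mean a lower fusion over vector ratio in U251 than in the clones. The difference between the lines would have list medians of 0.0998 for ERK output, 0.130 for hypoxia and glycolysis, 0.0662 for STAT3 targets and -0.0851 for mitochondrial respiration, the 4 lists that camera then called (adjusted p = 0.0126 to 0.0351; adjusted p = 0.442 to 0.701 with an estimated correlation).

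**Figure D4:**
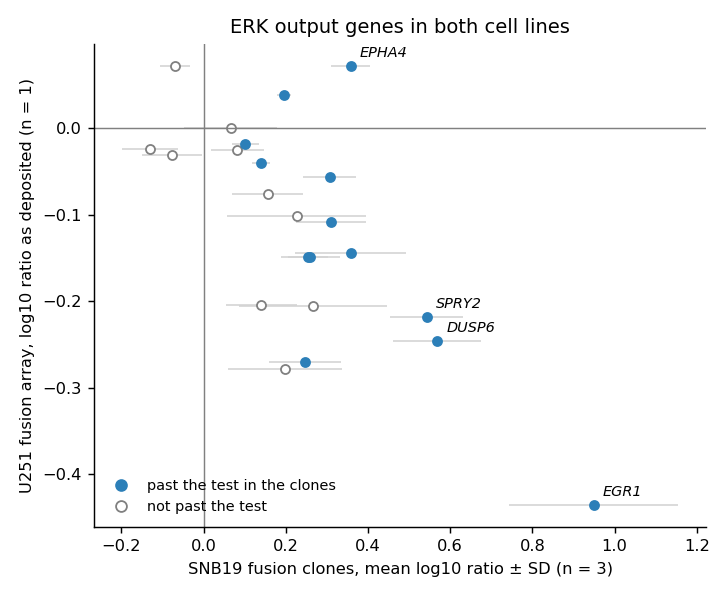
ERK output genes in the SNB19 fusion clones (horizontal axis, mean log10 ratio ± SD over 3 clones) and on the U251 fusion array (vertical axis, log10 ratio as deposited, direction not settled); filled dots passed the test in the clones. EGR1 lies at 0.949 and -0.435, and 19 of the 23 genes lie below 0 on the vertical axis.

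For wild-type FGFR3 and wild-type TACC3, the array from each line served as a replicate, and no gene passed against the vector. FGFR3 gave 0 of 17614 genes (smallest adjusted p = 0.151, 1961 unadjusted) and TACC3 0 (smallest adjusted p = 0.115, 2305 unadjusted). The values that follow did not pass and are as deposited. On the FGFR3 arrays the largest ratios shared by both lines were those of GRIN3B (0.558), the purinergic receptor P2RX6 (0.525) and LIN28A (0.507), and TRIM49 (-0.968), OR4C46 (-0.702) and NPTX2 (-0.637). On the TACC3 arrays they were those of GCGR, the glucagon receptor (0.944, from 1.31 in SNB19 and 0.577 in U251), PI16 (0.650) and APOL5 (0.607), and TRIM49 (-0.924), CLCA3P (-0.869) and TCL1A (-0.691). Each gene named here kept 1 sign on all Cy5 arrays, whatever the construct. TRIM49 lay between -1.21 and -0.766 there, CLCA3P between -0.902 and -0.529, OR4C46 between -0.833 and -0.528 and NPTX2 between -0.817 and -0.581. These were thus not particular to 1 construct. Without 1 of the wild-type arrays its construct is left with 1 array and no replicate. Leaving out probes at 0 on any array gave 2 for FGFR3 (CFAP43, -0.897, and LINC00484, -0.834, named after their values were seen) and 14 for TACC3, and leaving out the U251 TACC3 array gave 197 for TACC3.

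Mitosis and spindle genes had the largest list shift on the wild-type arrays. Their median was -0.143 for FGFR3 (camera adjusted p = 0.0158; adjusted p = 0.765 with an estimated correlation) and -0.131 for TACC3 (adjusted p = 0.00756; adjusted p = 0.985 with an estimated correlation), with 0 genes past the test over all genes or adjusted over the list alone. The shift lay in SNB19, where the medians were -0.282 (FGFR3) and -0.300 (TACC3), below all 10000 random lists, whereas in U251 they were 0.0263 and 0.0161. TOP2A, the topoisomerase of dividing cells, was at -0.416 and -0.528 in SNB19, and the checkpoint kinase TTK at -0.422 and -0.383. The clones, of opposite dye, gave -0.0281 for the same list. Camera also called mesenchymal and matrix genes for FGFR3 (median -0.0531, adjusted p = 0.0279; adjusted p = 0.718 with an estimated correlation), led by the cadherin CDH11 at -0.498 and fibronectin, FN1, at -0.345. For TACC3 it called ribosomal proteins (-0.0704, adjusted p = 0.0229; adjusted p = 0.434 with an estimated correlation), led by RPS16 at -0.201. The mitosis call was lost without the SNB19 array of each construct (adjusted p = 0.846 for FGFR3 and adjusted p = 0.989 for TACC3). The mesenchymal call was lost without the SNB19 FGFR3 array (adjusted p = 0.941) or the U251 TACC3 array (adjusted p = 0.0512). Its median was -0.0127 without the SNB19 FGFR3 array and -0.158 without the U251 FGFR3 array, so it rested on SNB19. The ribosomal call was lost without the SNB19 TACC3 array (median -0.0318, adjusted p = 0.0578) or the U251 TACC3 array (-0.0954, adjusted p = 0.124). Adjusted over the list alone, the neural and glial genes NCAN (0.379), DCX (0.305), BCAN (0.153) and S100B (-0.299) passed for FGFR3, and SREBF2 (0.252) of cholesterol synthesis for TACC3.

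Wild-type FGFR3 minus wild-type TACC3 asked which genes had different ratios with the 2 constructs, on 4 arrays of the same dye orientation. No gene passed (0 of 17614, smallest adjusted p = 0.935, 515 unadjusted). Scaling the arrays gave 1 gene (HSPB2, -1.09) and leaving out the U251 TACC3 array gave 5 (BOLL, CXorf65, GMCL2, MTMR7 and SLAMF6, at -1.72 to -0.970 and named after their values were seen). The largest differences shared by both lines did not pass. The sizes were those of the small heat shock genes HSPB2 (-1.42) and CRYAB (-0.623), the matrix Gla protein MGP (-0.753), and DISP3 (0.657), ZKSCAN8 (0.581) and TBC1D27P (0.558). MGP was at -1.07 on the SNB19 FGFR3 array against -0.267 on that of U251. TBC1D27P was at -0.407 on the U251 TACC3 array against 0.206 on that of SNB19, so both rested partly on 1 array. Mesenchymal and matrix genes had a median difference of -0.0677, with 5 of 27 positive (camera adjusted p = 3.51e-04; adjusted p = 0.257 with an estimated correlation), led by COL1A2 at -0.432 and CHI3L1 at -0.431. Cholesterol synthesis (-0.0488, adjusted p = 0.0319; adjusted p = 0.377 with an estimated correlation) and STAT3 targets (-0.0273, adjusted p = 0.0345; adjusted p = 0.257 with an estimated correlation) were also called. The mesenchymal call was lost without the SNB19 FGFR3 array (median -0.0326, adjusted p = 0.503) or the U251 TACC3 array (-0.0732, adjusted p = 0.203), and its median was -0.107 without the SNB19 TACC3 array and -0.128 without the U251 FGFR3 array. The cholesterol call was lost without any 1 array other than that of U251 FGFR3 (adjusted p = 0.231 to 0.544), and its median was 0.00212 without the SNB19 FGFR3 array. The STAT3 call was lost without any 1 of the 4 (medians -0.0818 to -0.00682, adjusted p = 0.104 to 0.584).

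The fusion was compared with each wild-type construct in the model with a dye term, where the estimate is the U251 fusion array minus the mean of the SNB19 and U251 arrays of the wild-type construct. Cell line is thus mixed into it. No gene passed against FGFR3 (smallest adjusted p = 0.768, 456 of 17614 unadjusted) or against TACC3 (smallest adjusted p = 0.802, 563 unadjusted), and scaling the arrays gave 94 and 148. Leaving out the U251 TACC3 array gave 5 against TACC3 (BOLL, CXorf65, GMCL2, MTMR7 and SLAMF6, at -1.79 to -0.970 and named after their values were seen). These estimates do not depend on how the Cy3 arrays are turned. Against FGFR3 the largest differences, none past the test, were those of the muscle creatine kinase CKM (0.884), PDGFRB (0.778), INHBA (0.685), NECAB2 (-0.839), the antigen gene MAGEB2 (-0.777) and ANXA10 (-0.724). Most of these rested on 1 wild-type array. On the SNB19 FGFR3 array INHBA was at -1.24, PDGFRB at -1.44, MAGEB2 at 1.43, ANXA10 at 0.959 and NECAB2 at 0.596, and on the U251 FGFR3 array CKM was at -1.81. Without the SNB19 FGFR3 array the difference was 0.0535 for INHBA, 0.0152 for PDGFRB, -0.0431 for MAGEB2, -0.327 for ANXA10 and -0.176 for NECAB2, and without the U251 FGFR3 array that of CKM was -0.0472 and that of NECAB2 -1.50. Without the dye term INHBA turned to -0.387. Against TACC3 they were those of TDRP (0.678), CIMAP1A (0.671), ABCA11P (0.627), HSPB2 (-1.08), SLAMF6 (-0.970) and NECAB2 (-0.838). Without the SNB19 TACC3 array SLAMF6 was at -0.151, ABCA11P at 0.277, HSPB2 at -0.611 and NECAB2 at -0.454. The median difference of mitosis and spindle genes was 0.174 from FGFR3 (camera adjusted p = 2.54e-04; adjusted p = 0.762 with an estimated correlation) and 0.175 from TACC3 (adjusted p = 2.29e-04; adjusted p = 0.606 with an estimated correlation), 22 of 24 genes positive in each. The SNB19 wild-type medians of -0.282 and -0.300 enter these differences. Without the SNB19 FGFR3 array the median difference from FGFR3 was 0.0439 (adjusted p = 0.816), and without the SNB19 TACC3 array that from TACC3 was 0.0348 (adjusted p = 0.461), so the call was lost within U251. The median difference of interferon response genes from FGFR3 was 0.0769 (adjusted p = 0.00999; adjusted p = 0.762 with an estimated correlation), led by MX1 at 0.430 and RSAD2 at 0.411. It was 0.188 without the SNB19 FGFR3 array (adjusted p = 2.97e-08; adjusted p = 0.131 with an estimated correlation) and -0.0206 without the U251 FGFR3 array (adjusted p = 0.816).

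Across genes the arrays fell into sets by line and, within SNB19, by dye and construct. Dye and construct cannot be told apart there, since all SNB19 fusion arrays were in Cy3 and all SNB19 wild-type arrays in Cy5. The clones correlated with each other at r = 0.633 to 0.808, and the SNB19 FGFR3 and TACC3 arrays with each other at r = 0.685. The mixture correlated with the clones at only r = 0.430 to 0.465. The 3 U251 arrays correlated at r = 0.279 to 0.398. Clones and Cy5 arrays correlated at r = -0.0994 to 0.101 as deposited, and turning the Cy3 arrays changes only the sign. The labels do not say whether arrays of a line shared 1 vector RNA. As a reference, 2 simulated arrays with 1 shared reference, no effect and equal spread in every channel correlated at 0.508. The clones and the SNB19 wild-type arrays, of opposite dye, correlated at r = -0.0429 to 0.0173.

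**Figure D5:**
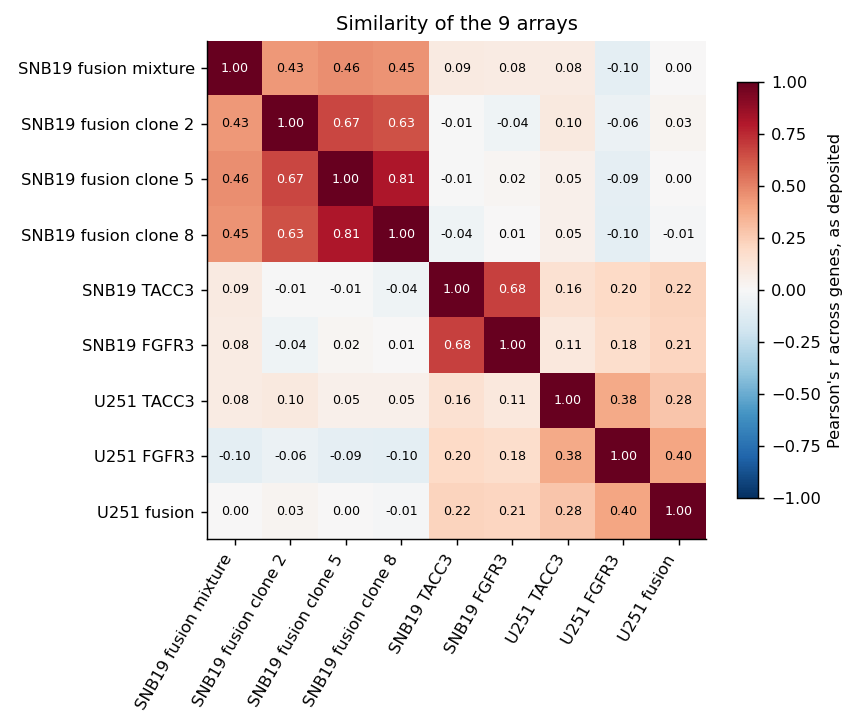
Pearson's r across 17676 genes between each pair of the 9 arrays (both axes), with values as deposited and colours from -1 to 1. The clones form a block at 0.633 to 0.808 and the SNB19 wild-type arrays a pair at 0.685, with values near 0 between them.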

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

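Apart from the share and the spread of olfactory receptor genes, the tests of explanations in this part were chosen only after the result was seen. Gene lists stand out here for their difference between the U251 and SNB19 fusion arrays as deposited. Features without a gene name stand out for a signal outside the named genes.

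As deposited, the median log10 ratio of ERK output genes differed between U251 and the SNB19 clones by -0.345. Those of hypoxia and glycolysis differed by -0.126, NF-kB and inflammatory cytokines by -0.169, STAT3 targets by -0.110 and stress response by -0.0848. Each passed camera and none passed with an estimated correlation, while fry called ERK output, NF-kB and STAT3 targets (adjusted p = 0.0236 each). If the Cy5 arrays run vector over transfected, these values describe the sum of both lines, not how they differ. With the Cy3 signs turned the ERK output difference was 0.0998. It would then run vector over transfected and so place U251 below the clones. The NF-kB and stress lists were no longer called with these signs. Cell line and dye orientation cannot be told apart in this contrast, and the ERK output median was also negative as deposited on the U251 FGFR3 and TACC3 arrays.

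Of 10842 tested features without a gene name, 1874 (17.3%) passed limma in the clones, 799 higher and 1075 lower. Feature 28766, picked after its values were seen, lay between -1.24 and -0.788 on all 9 arrays.

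A large share of genes passed in the clones, and a single cause behind all of them was looked for. A dye bias of each probe should move all arrays, but over the 4743 called genes the mean of the U251 arrays had a slope of -0.0148 (SE 0.00648) on the clone mean. Vector RNA common to all SNB19 arrays, which the labels do not state, should move the SNB19 wild-type arrays, whose slope was -0.0421 (SE 0.0156), and a fusion effect shared by both lines should appear in U251, where the slope was -0.00377 (SE 0.00801). These slopes argue against each of them as the whole cause, and leave open a dye bias present in the clones alone, another batch of vector RNA, and an effect of the fusion in SNB19 only. Signal of genes that are not expressed stays open, since 20.7% of the olfactory receptor genes were called against 28.1% of all genes.

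The mixture followed the mean of the clones it pools less closely than each clone followed the others. Unequal shares of the clones are argued against by a correlation of 0.501 with the best weights, below the lowest left-out clone at 0.682. Noise of the mixture array is argued against only for olfactory receptor genes, whose spread was 0.909 times that of the highest clone. Over all features the SD was 0.240 on the mixture and 0.149 to 0.170 on the clones, so noise in other genes may contribute. A different growth state of the mixture culture may contribute, as the DNA replication list had a median of -0.375 on that array, but no value from another mixture decides it. No biological explanation was tested.

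TACC3 was above 0 on the Cy3 arrays and below 0 on the Cy5 arrays in all 7 arrays whose construct carries it. A candidate explanation is that all 9 ratios run Cy3 over Cy5, the reverse of the software's usual output. Probes with a dye bias would then keep 1 sign, and 91 features did so on all 9 arrays at sizes of at least 0.1. The expected number was 51.5 if the signs on the Cy3 arrays were independent of those on the Cy5 arrays. Of the 91 features, 78 were negative (25.8 expected) and 13 positive (25.7 expected). If all ratios ran transfected over vector, such probes would change sign with the dye, and 41 did against 51.6 expected, 33 of them positive on Cy3 (27.0 expected) and 8 negative on Cy3 (24.6 expected). For each reading 1 count lay above and 1 below the expected number. The largest departure was the 78 features negative on all 9 arrays, which goes with Cy3 over Cy5. The 13 positive ones, below the expected number, go against it. Any correlation between the Cy3 and the Cy5 arrays makes the expected numbers approximate, so the counts do not decide between the readings. TACC3 was at -0.574, -0.352 and -0.168 on the Cy5 arrays whose construct carries it. A construct can only add its own transcript. If the probe reads the construct, these values argue against all 9 ratios running transfected over vector. They rest on 1 probe, and no biological explanation was tested.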

How the results depend on the processing

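Leaving out each wild-type array, list tests with the Cy3 signs turned and centring the U251 fusion array were tests chosen only after the data were seen. Without 1 wild-type array its construct has 1 array left, so such counts have no replicate. In the clones the count of 4743 genes became 8686 probes when each probe was tested, 2474 with the mixture added and 680 in the fit over 8 arrays, and it ranged from 0 to 3456 when each clone was left out, with fewer degrees of freedom. The other comparisons had counts of 0. With arrays scaled to 1 median size the counts were 1008 for the fusion in both lines, 1011 for U251 against SNB19, 94 for the fusion against FGFR3, 148 for the fusion against TACC3 and 1 for FGFR3 against TACC3. With probes at 0 on any array left out they were 2 for the fusion in both lines, 2 for FGFR3 and 14 for TACC3, and each probe tested gave 1 for the fusion in both lines. With each array left out they ranged from 0 to 197 for TACC3, from 0 to 5 for FGFR3 against TACC3 and from 0 to 5 for the fusion against TACC3. Of 6 gene lists, 0 remained with an estimated correlation, while fry called 10, which held 5 of the 6 but not hypoxia and glycolysis (adjusted p = 0.0802). In the other comparisons fry called 3 lists for U251 against SNB19 and 0 elsewhere. For these changes the cause was not tested.

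Reversed values were those of genes that had not passed and of TACC3 in mixed dyes. FGFR3 in the clones ranged from -0.0106 to 0.0460 over left-out clones. On the wild-type FGFR3 arrays FGFR3 was at 0.000645 with the median subtracted, 0.0106 scaled and 0.0209 with the dye term, and from -0.0547 to 0.0304 over left-out arrays. There TACC3 was at 0.0141 scaled and 0.664 with the dye term, and from -0.0672 to 0.0388 over left-out arrays. On the wild-type TACC3 arrays TACC3 was at 0.418 with the dye term. For the fusion in both lines TACC3 was at -0.170 scaled and -0.678 with the Cy3 signs turned, and for U251 against SNB19 at 0.208 with them turned. Without the dye term the fusion against FGFR3 gave INHBA -0.387, FGFR3 0.00876 and TACC3 0.457, and the fusion against TACC3 gave TACC3 0.703. Over left-out arrays the fusion against FGFR3 ranged from -0.0472 to 1.81 for CKM and from -0.0834 to 0.00173 for FGFR3. Turned signs and the dye term change the values by construction, and otherwise the cause was not tested.

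Among the remaining values of named genes and lists, 826 kept direction and side of the threshold, 65 lost the call, 13 gained it and 19 counts of lists moved. Some settings cannot change an estimate: leaving out any clone left CKM at 0.884 in the fusion against FGFR3. The 25 genes called in the clones kept their direction in each setting that measured them, and 0 passed without clone 5 or clone 8. Apart from TACC3, they were named for 1 sign in the 3 clones and the mixture, and TACC3 had 1 sign there too. Leaving out a clone, adding the mixture or the fit over 8 arrays could therefore not reverse them. Signal over background is not given in the sources used here, so its limit on weak genes is unknown.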

Other observations

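The test of the ERK output hypothesis in this part was chosen only after the result was seen. The values are of single arrays without replicates. On the mixture array genes of cell division were low and stress genes high, which the clones did not show to that extent. The DNA replication list had a median log10 ratio of -0.375 with 1 of 24 genes positive, and the mitosis and spindle list -0.209 with 0 of 24 positive, both below all 10000 random lists. MCM5 of the replicative helicase was at -0.612, thymidylate synthase, TYMS, at -0.590 and the proliferation marker MKI67 at -0.585, against clone means of -0.185, -0.102 and -0.0553. The stress response list stood at 0.419 with 17 of 18 genes positive, above all random lists. DDIT3, a transcription factor of the unfolded protein response, was at 0.636, the asparagine synthetase ASNS at 0.618 and the chaperone HSPA5 at 0.433, against clone means of -0.00849, 0.166 and 0.00773. The p53 target list was at 0.232 and the STAT3 target list at 0.204, with GDF15 at 0.935.

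On the U251 arrays, given as deposited with no settled direction, interferon response genes had a median of -0.143 with FGFR3 (2 of 24 positive) and -0.0540 with TACC3 (5 of 24 positive), against 0.0232 with the fusion. IFI27, an interferon-induced mitochondrial protein, was at -0.647 with FGFR3 and -0.692 with TACC3. Neural and glial genes had a median of 0.0888 with TACC3, with 18 of 22 positive, GFAP at 0.307, FABP7 at 0.297 and the oligodendrocyte factor OLIG2 at -0.504.

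A hypothesis on the ERK output list follows from the reading in which all ratios run Cy3 over Cy5, which the 91 features of 1 sign on all 9 arrays leave open. The U251 fusion array would then have a median of 0.102 with the sign turned, and ERK output genes might be higher in fusion cells of both lines. Of the 13 genes called in the clones, 11 were below 0 as deposited on the U251 fusion array, where 42.6% of all genes were. They belong to the list whose shift on that array prompted the hypothesis, so this count is no separate support. The same turn gives 0.0772 for TACC3 and 0.0419 for FGFR3 in U251, so the shift would not be specific to the fusion in that line. In SNB19 it gives -0.0453 for TACC3 and 0.0555 for FGFR3. The SNB19 fusion mixture, in Cy3 and not turned, had a median of 0.0369 (percentile 86.6 of random lists), against 0.227 in the clones.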
